A study of Dehalococcoides mccartyi CBDB1 with 6 samples.

How the data were processed

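Total RNA from *Dehalococcoides mccartyi* CBDB1 was sequenced in 6 libraries, 3 per electron acceptor. Per the labels' protocols, cultures of 150 mL grew at 30 °C with hydrogen, 5 mM acetate and a hexadecane phase with the trichlorobenzene of the group at 400 mM, which gave a nominal 10 mM. RNA was treated with DNase, 400 ng per library were fragmented with magnesium ions and passed through a small RNA ligation kit with 15 PCR cycles. The labels' protocols name no step that removes rRNA. Groups and replicate numbers were taken from the sample titles.

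The deposited values are expected counts, that is read counts per annotated feature that need not be whole: 39.1% of the values were not whole (tolerance 1e-06), and the step that gave fractions is not given in the sources used here. Per the submitters' processing notes, bcl2fastq 2.20.0.422, cutadapt 1.15 and DESeq2 1.24.0 were used, with no roles given. The aligner, the counting tool, its use of strand and the treatment of reads with several places are not given in the sources used here. Per the file headers, features lie on the chromosome record NC_007356.1, and positions are printed as in the deposited table. Values of near-identical copies and of overlapping or antisense genes are uncertain for that reason. The annotated neighbours that overlapped named genes were on the same strand and shared at most 89 bases.

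The table had 1501 features. The 7 features without a locus name, all riboswitches, stayed out of library sizes and tests; they held 0.114% of counts outside rRNA. Features of the same locus were summed for 2 loci, which gave 1492 loci. Expected counts were rounded to whole numbers and the rRNA loci were left out, which left 1489. Genes with low counts were removed with filterByExpr, and 1363 genes remained, of which 1309 were protein-coding.

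Genes were tested with edgeR 4.0.16 (quasi-likelihood fit and test, TMM normalization, electron acceptor as the only term) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic, and 95% confidence intervals use the matching degrees of freedom. CPM are relative to the TMM-scaled library size. The names and search terms of 20 gene lists had been fixed before the data were examined, as had the tests, the alternatives and the rule for named genes. How the terms were matched was chosen after the product names had been seen: upper and lower case were kept apart, after a first match that ignored case had been looked at; only protein-coding genes and pseudogenes were matched; and the stable RNA list was taken by feature type, without rRNA. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (limma 3.58.1). Shares of counts were compared by an exact two-sided permutation test over all assignments of the 6 libraries, which cannot give less than 0.1. Neighbouring calls were compared with 100000 permutations of the calls among tested genes in chromosome order, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9.

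The rule named 83 genes. It took every called *rdhA* gene; the 10 genes with the largest log2 fold change in each direction among called genes with a mean of at least 10 CPM and no overlap of the groups; cbdbA84, cbdbA187, cbdbA1453, cbdbA1624 and cbdbA1625 whatever their result; the 5 genes with the highest mean CPM; up to 4 members with the smallest p for each called list; and up to 2 for each list without a call.

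Data for the comparison of 1,2,4-TCB with 1,2,3-TCB were simulated with 200 changed genes in each of 5 runs and the real effective library sizes. The test recovered 72.6% of genes changed 2-fold and 99.2% of genes changed 4-fold, and it called 0.601% of the unchanged genes. On average 1331 genes were tested. Apart from a planted fall of the ATP synthase list, changes went up and down in equal number at a common dispersion. In the real data 1011 genes were called, so these rates need not hold for them. A count of 3 corresponds to 1.61 to 2.06 CPM in the libraries with 1,2,3-TCB and to 6.51 to 8.04 CPM with 1,2,4-TCB, so that low transcripts are measured less precisely with 1,2,4-TCB. PCR reads without molecular identifiers are not independent molecules, so such floors and intervals cover counting error only.

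Replicate libraries were compared before they were averaged. The chi-square per degree of freedom between libraries of the same acceptor was 5.26 to 31.2, above sampling noise for every pair, so that no library was counted as a copy of another, and it was 339 to 439 between acceptors. Alternatives were RLE and upper quartile normalization, library size alone, no filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, a replicate block, rRNA kept, all stable RNA left out, a minimum change and leaving out each library. Scaling to all counts with rRNA kept, counts left unrounded, list terms matched without regard to case, the stable RNA list taken by its terms, and camera after the median of each of 5 classes of coding length was taken off in each library were added after the data were seen. Genome sequence was not used here.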

Results

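The transcriptome of *Dehalococcoides mccartyi* strain CBDB1, an anaerobic bacterium that respires organohalides with hydrogen as electron donor, was measured by RNA sequencing in 6 libraries. The cultures had been grown with 1,2,3-trichlorobenzene (1,2,3-TCB) or with 1,2,4-trichlorobenzene (1,2,4-TCB) as the electron acceptor, at the same nominal concentration of 10 mM, and 3 libraries were made per acceptor. The acceptors are positional isomers that differ in where the third chlorine sits on the ring. Cells were harvested while growth passed from the exponential into the stationary phase, at a single time point, and no culture without a trichlorobenzene is part of the design. The libraries held 18527033 to 20889843 counts with 1,2,3-TCB and 20172474 to 21389449 with 1,2,4-TCB. Because rRNA took most of them, 801449 to 998303 counts per library fell in the tested genes with 1,2,3-TCB and 671881 to 821255 with 1,2,4-TCB. The labels call the libraries replicate samples and do not say that each came from its own culture, so p-values measure the spread between these samples. Growth state at harvest is not given per culture, so differences between the acceptors below cannot be told apart from differences in growth state.

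The first question was how the RNA classes were divided between the acceptors. Protein-coding genes held 3.20% ± 0.0875 (SD, n = 3) of all counts with 1,2,3-TCB and 0.857% ± 0.140 (SD, n = 3) with 1,2,4-TCB, which was 3.73 times lower. The share of the putative 6S RNA sRNA1, a kind of small RNA known in many bacteria to bind RNA polymerase, went the other way, from 0.299% ± 0.0348 to 1.28% ± 0.0712 of all counts. A putative small RNA of no named class, sRNA3 (positions 1327943 to 1328253, plus strand), held 0.00400% ± 0.000990 with 1,2,3-TCB and 0.146% ± 0.0388 with 1,2,4-TCB, 36.5 times more. The share of rRNA was 95.5% ± 0.227 and 96.5% ± 0.273. In each of these classes the 3 libraries of one acceptor lay apart from the 3 of the other, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The share of tRNA genes, 0.386% ± 0.187 against 0.464% ± 0.135 (exact permutation p = 0.7), and that of the transfer-messenger RNA ssrA, 0.305% ± 0.0185 against 0.324% ± 0.0349 (exact permutation p = 0.5), overlapped between the acceptors.

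**Figure D1:**
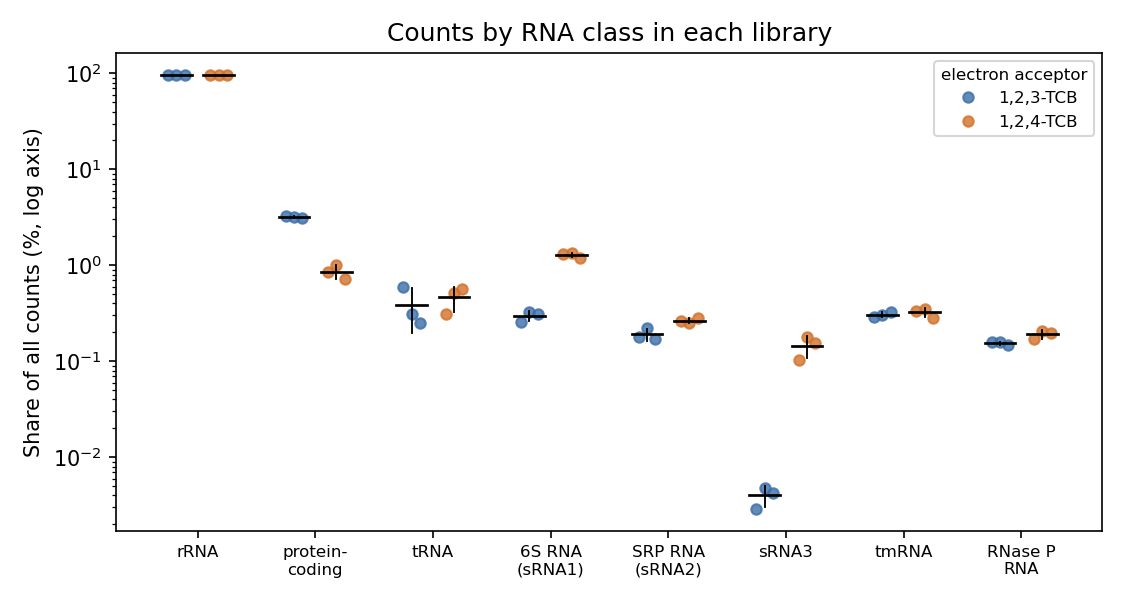
Share of all counts by RNA class in each library, in percent on a log axis, for 1,2,3-TCB (blue) and 1,2,4-TCB (orange). Points are libraries, horizontal bars are means and vertical lines are 1 SD (n = 3). Protein-coding genes held 3.20% of all counts with 1,2,3-TCB and 0.857% with 1,2,4-TCB, and sRNA3 held 0.00400% and 0.146%.

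Genes were then compared one by one, as 1,2,4-TCB over 1,2,3-TCB, with rRNA left out. Of 1363 genes tested, 506 were higher and 505 were lower with 1,2,4-TCB (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 352 did not pass. The change was at least 2-fold for 372 of the higher and 383 of the lower genes. The libraries of the acceptors did not overlap for 77.0% of the genes tested, where chance gives 10%. These calls are relative to the typical gene of the same library, because with TMM normalization the median log2 ratio of all tested genes was -0.01. On the scale of the non-rRNA total the median gene shifted by -1.75, and on the scale of all counts, rRNA included, it shifted by -2.12 on the log2 scale. Accordingly, 118 genes were called higher and 1018 lower with the non-rRNA library size alone, and 87 higher and 1096 lower when rRNA was kept and all counts set the scale. Of 504 genes called higher that were tested on both scales, 343 lay below 0 on the scale of all counts. Fold changes below are on the TMM scale, and the value on the scale of all counts is given for the named genes whose direction turned there.

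The reductive dehalogenase genes (*rdhA*), which encode the terminal reductases of organohalide respiration, were the first group of interest. Of 30 annotated *rdhA* genes 17 had enough counts to be tested, 10 were higher and 3 were lower with 1,2,4-TCB, and the same 10 and 3 counts were obtained when p was adjusted over the list alone. With all counts as the scale only 3 of 15 tested were higher, cbdbA1588, cbdbA1508 and cbdbA1638, and 6 were lower, so the direction of the group turned there. The 13 untested genes reached at most 26 counts in any library. The largest change was that of cbdbA1588 (positions 1274257 to 1275744, minus strand), which rose from 11.96 ± 1.87 to 4886 ± 1888 CPM (SD, n = 3 each), a log2 fold change of 8.66 ± 0.43 (SE; edgeR adjusted p = 6.7e-07). The gene cbdbA1638 (1325086 to 1326588, minus strand) rose from 35.6 ± 3.11 to 1763 ± 731 CPM, 49.5-fold (edgeR adjusted p = 1.2e-06). The gene cbdbA1508 (1193343 to 1194734, minus strand) rose from 4.93 ± 1.89 to 470 ± 228 CPM (edgeR adjusted p = 3.1e-06). Its small neighbour cbdbA1507 carried the same values as cbdbA1587 beside cbdbA1588 in all 6 libraries, and the level of cbdbA1508 is uncertain. Counts of cbdbA1588, cbdbA80, cbdbA1453 and cbdbA1624 were also not whole in some libraries. How reads with several places were treated is not given, so these levels carry that limit too.

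Smaller increases were found for cbdbA1618 (6.27-fold) and cbdbA1624 (4.57-fold). The genes cbdbA1550 (3.86-fold), cbdbA1542 (3.67-fold), cbdbA243 (3.31-fold), cbdbA1455 (2.95-fold) and cbdbA1582 (2.56-fold) were also higher. The edgeR adjusted p lay between 8.9e-06 for cbdbA1618 and 0.028 for cbdbA1582. Some of these folds rest on few counts. With 1,2,3-TCB and 1,2,4-TCB in turn, cbdbA1542 had 10, 5 and 14 against 6, 11 and 10 counts. For cbdbA1550 they were 16, 13.75 and 8.75 against 12.5, 17 and 9.25, and for cbdbA243 25, 20 and 14 against 13, 23 and 13. The libraries of the acceptors overlapped for cbdbA1582. The calls of cbdbA243, cbdbA1455, cbdbA1542, cbdbA1550, cbdbA1582 and cbdbA1624 were lost with the non-rRNA library size alone. On the scale of all counts cbdbA243, cbdbA1455, cbdbA1550 and cbdbA1582 turned to log2 fold changes of -0.37, -0.55, -0.14 and -0.75, and cbdbA1542 was not tested. The call of cbdbA1618 was lost there (log2 fold change 0.53, edgeR adjusted p = 0.055; 8.5e-20 to 0.055 over its alternatives). The call of cbdbA1582 was also lost without 1,2,3-TCB replicate 2 (edgeR adjusted p = 0.064), 1,2,4-TCB replicate 1 (0.14) or 1,2,4-TCB replicate 3 (0.094), its log2 fold change of 1.36 was 1.98 without 1,2,3-TCB replicate 3, and its adjusted p lay between 0.0022 and 0.45 over its alternatives. The 3 lower members were cbdbA187 (170338 to 171705, plus strand; 14.0-fold, edgeR adjusted p = 4.3e-05), cbdbA80 (61449 to 62939, plus strand; 5.29-fold, edgeR adjusted p = 4.0e-04) and cbdbA1453 (1146028 to 1147515, minus strand; 2.05-fold, edgeR adjusted p = 0.0068). The gene cbdbA84, which encodes the chlorobenzene reductive dehalogenase CbrA (67523 to 68989, plus strand), had 6935 ± 848 CPM with 1,2,3-TCB and 7381 ± 1075 CPM with 1,2,4-TCB. Its log2 fold change was 0.09 (95% confidence interval -0.40 to 0.58; edgeR adjusted p = 0.73), but -0.12 with upper quartile normalization, -0.04 without 1,2,4-TCB replicate 3 and -2.04 on the scale of all counts. The MarR-type regulator gene cbdbA1625 beside cbdbA1624 had a log2 fold change of 0.77 (95% confidence interval -0.12 to 1.66; edgeR adjusted p = 0.10), and of -1.32 on the scale of all counts. On the TMM scale it passed without 1,2,3-TCB replicate 3 (0.035) or without 1,2,4-TCB replicate 1 (0.033; 0.0058 to 0.34 over its alternatives).

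The make-up of the *rdhA* transcripts differed accordingly. Among counts in *rdhA* genes, cbdbA80 held 55.8% ± 11.2 (SD, n = 3) with 1,2,3-TCB and 11.1% ± 4.15 with 1,2,4-TCB, and cbdbA1588 held 0.0555% ± 0.0109 and 23.6% ± 5.56. The share of cbdbA84 was 32.5% ± 7.19 and 37.4% ± 6.78 (exact permutation p = 0.5). All *rdhA* genes together held 3.97% ± 0.380 of non-rRNA counts with 1,2,3-TCB and 1.09% ± 0.202 with 1,2,4-TCB (exact two-sided permutation p = 0.1, the smallest possible). As a share of protein-coding counts alone the values were 5.63% ± 0.418 and 4.56% ± 0.996, a log2 ratio of -0.30 in place of -1.86.

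**Figure D2:**
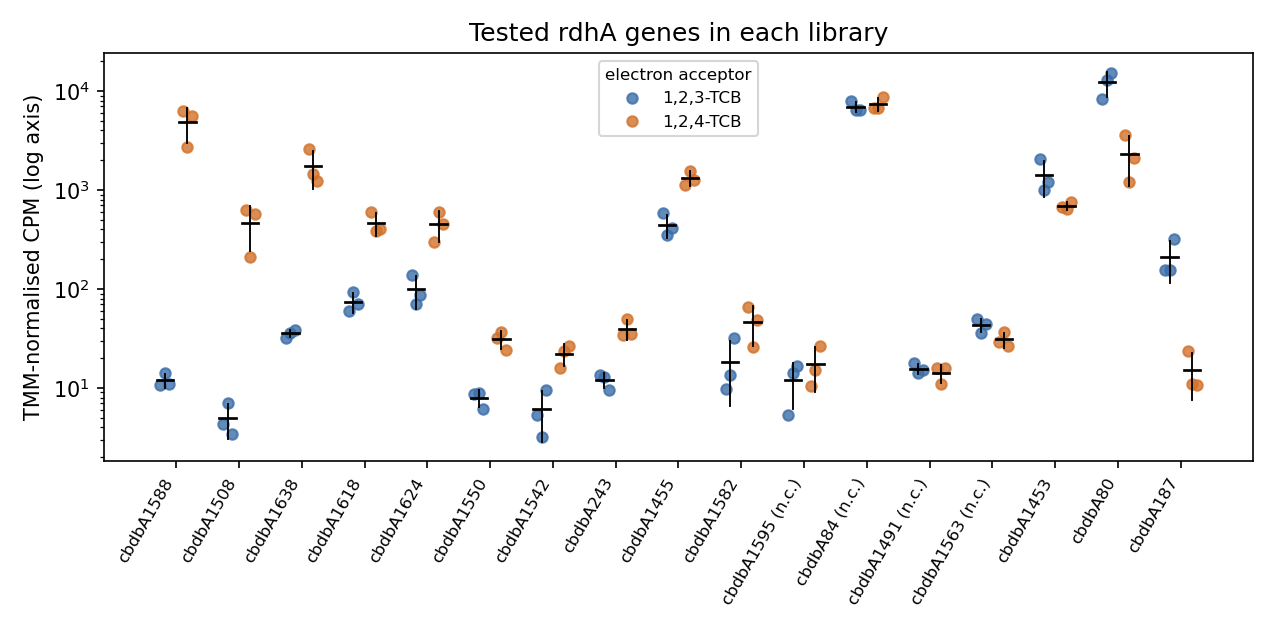
TMM-normalised CPM (log axis) of the 17 tested *rdhA* genes in each library, ordered by fold change; points are libraries, horizontal bars are means, vertical lines are 1 SD (n = 3) and n.c. marks genes that did not pass the test. The gene cbdbA1588 rose from 11.96 to 4886 CPM, while cbdbA84 lay at 6935 and 7381 CPM; on the scale of all counts cbdbA84 had a log2 fold change of -2.04.

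Outside the *rdhA* genes, the largest increases with 1,2,4-TCB were those of 7 protein-coding genes, 4 of them for hypothetical proteins, and of sRNA3. The small hypothetical genes cbdbA1507 and cbdbA1587, which have identical values, went from 4.25 to 780.75 summed counts each. Relative to the TMM-scaled library sizes this was a ratio of 738, with a 95% counting interval of 305 to 2885. The membrane anchor gene cbdbA120 of a NrfD/PsrC-type molybdoenzyme rose 69.2-fold (edgeR adjusted p = 3.7e-07). The peptide ABC transporter gene cbdbA1039 rose from 116 ± 87.2 to 10164 ± 2071 CPM, a log2 fold change of 6.45, which became 7.09 without 1,2,3-TCB replicate 2. The genes cbdbA1593, for a NifB/NifX-type cluster-binding protein, and cbdbA737 and cbdbA1637, both for hypothetical proteins, rose 103-fold, 92.5-fold and 110-fold. The small RNA sRNA3 rose 156-fold on this scale.

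Of the 10 largest decreases among called genes with a mean of at least 10 CPM and no overlap of the groups, 5 lay in one stretch between positions 687728 and 696816, where 9 neighbouring genes for complex I-like subunits, iron-sulfur proteins and a nickel-dependent hydrogenase fell together. Within it cbdbA844, for a NADH-quinone oxidoreductase subunit B family protein, fell 24.7-fold, to 6.76 ± 2.10 CPM (edgeR adjusted p = 1.3e-06), and cbdbA845, cbdbA843, cbdbA848 and cbdbA851 fell 15.9-fold, 12.8-fold, 17.9-fold and 19.1-fold. Without 1,2,4-TCB replicate 3 the log2 fold change of cbdbA848 moved from -4.16 to -5.05. The glutamine synthetase family gene cbdbA1568 and its overlapping neighbour cbdbB41 fell 13.4-fold and 19.4-fold. These folds rest on few counts with 1,2,4-TCB: over the 3 libraries cbdbA844, cbdbA851 and cbdbB41 had 8.5, 4 and 5 counts, with 95% counting intervals of the fold of 12.8 to 58.9, 7.70 to 73.5 and 8.49 to 61.8, and cbdbA845, cbdbA848 and cbdbA843 had 14, 16.5 and 23 counts. The corrinoid synthesis gene cbdbA1067 (*cbiB*) fell 13.2-fold, and its log2 fold change of -3.73 was -4.34 without 1,2,4-TCB replicate 2. The arsenite efflux gene *arsB* had only 2 counts in all with 1,2,4-TCB against 208 with 1,2,3-TCB. Relative to the TMM-scaled library sizes it was 25.9-fold lower, with a 95% counting interval of 7.08 to 215. Counting intervals cover counting error only.

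Among the most abundant transcripts, sRNA1 rose from 36088 ± 6013 to 666834 ± 39176 CPM (18.5-fold, edgeR adjusted p = 1.9e-06). The putative SRP RNA sRNA2, the RNase P RNA *rnpB* and ssrA rose 6.06-fold, 5.41-fold and 4.58-fold on the TMM scale. On the scale of all counts the log2 fold change of sRNA1 was 2.10. Those of sRNA2 and *rnpB* were only 0.47 and 0.32 there (edgeR adjusted p = 0.0086 and 0.049). That of ssrA was 0.09 (edgeR adjusted p = 0.54, with 3.1e-39 to 0.54 over its alternatives). The most abundant protein-coding gene, cbdbA1368 for a fibronectin type III domain protein, had 52651 ± 6272 and 43208 ± 7996 CPM (log2 fold change -0.29, 95% confidence interval -0.83 to 0.26, edgeR adjusted p = 0.31), and with all counts as the scale it was lower (-2.40).

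Of 20 gene lists, 19 had members and were tested. With a preset correlation, camera called 4 lists higher and 7 lower. Another division of the same 6 libraries into 3 and 3, which mixed the acceptors, gave 13 called lists. With an estimated correlation camera called 0 of the 19 lists, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.297. For each called list this p is given beside its count. The fry test, which asks only whether the genes of a list move one way on balance, passed for 17 lists, and for 19 lists in its mixed form. It does not compare a list with other genes. Since 1011 of 1363 tested genes were called, passing it does not set a list apart. No list was chosen on these samples. The median log2 fold change of protein-coding genes went down with coding length, from 0.46 in the 262 shortest (69 to 423 bp) to -0.47 in the 262 longest (1281 to 4305 bp), and on the scale of all counts from -1.66 to -2.58. When the median of each of 5 length classes was taken off in each library, 9 of the 11 lists kept their camera calls at the preset correlation, and the aminoacyl-tRNA synthetase and acetyl-CoA lists lost theirs. Chaperone and protease genes rose in 12 of 16 cases and none fell (camera adjusted p = 0.0036; adjusted p = 0.371 with an estimated correlation), but on the scale of all counts only 4 were higher and 10 were lower. The DnaJ-type gene cbdbA1372 rose 43.7-fold, the Clp ATPase gene cbdbA1374 9.69-fold and the Hsp20 gene cbdbA909 7.92-fold. Of its members that do other work, *hypA* and cbdbA1400, which serve hydrogenase maturation, rose 7.31-fold and 2.33-fold, and the heme chaperone gene *hemW* and the iron chaperone gene cbdbA1151 rose 1.44-fold and 1.47-fold. On the scale of all counts cbdbA1400, *hemW* and cbdbA1151 turned to log2 fold changes of -0.89, -1.57 and -1.56. The chaperonin genes *groL* and cbdbA1392 (GroES) did not pass, with log2 fold changes of 0.37 and 0.11, which were -1.74 and -1.999 on the scale of all counts. Redox defence and iron-sulfur assembly genes rose in 10 of 11 cases and fell in 1, the thioredoxin reductase gene *trxB* (camera adjusted p = 0.0037; adjusted p = 0.330 with an estimated correlation), with 3 higher and 4 lower on the scale of all counts. Thioredoxin *trxA* rose 7.94-fold, the desulfoferrodoxin-domain gene cbdbA1720 6.61-fold, the peroxiredoxin gene cbdbA1669 6.21-fold and the superoxide dismutase gene cbdbA912 3.39-fold; cbdbA912 turned to a log2 fold change of -0.35 on the scale of all counts. Stable RNA genes other than rRNA were higher in 50 of 51 cases (camera adjusted p = 4.2e-08; adjusted p = 0.423 with an estimated correlation), and in 6 cases, with 2 lower, on the scale of all counts. The *rdhA* list itself had camera adjusted p = 0.048 (adjusted p = 0.297 with an estimated correlation), which was 0.051 without 1,2,4-TCB replicate 3, 0.059 with a mean of at least 50 counts and 0.060 with limma-voom (0.0013 to 0.297 over its alternatives).

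The lists called lower at the preset correlation were led by ribosomal proteins, ATP synthase and amino acid biosynthesis. All 8 ATP synthase genes fell (camera adjusted p = 5.0e-06; adjusted p = 0.297 with an estimated correlation), with *atpF* 9.21-fold, *atpG* 8.19-fold, cbdbA539 6.66-fold and *atpE* 6.46-fold lower. Ribosomal protein genes fell in 46 of 53 cases and rose in 1 (camera adjusted p = 7.4e-11; adjusted p = 0.297 with an estimated correlation), with *rplV* 6.35-fold, *rpsC* 6.30-fold, *rpsJ* 5.28-fold and *rplP* 4.68-fold lower. Amino acid biosynthesis genes fell in 34 of 54 cases and rose in 3 (camera adjusted p = 5.0e-06; adjusted p = 0.297 with an estimated correlation), among them the aromatic pathway genes cbdbA429 (7.33-fold), *pheA* (7.19-fold) and *aroA* (6.89-fold). Genes of twin-arginine and Sec translocation fell in 12 of 15 cases and rose in 2 (camera adjusted p = 0.0073; adjusted p = 0.297 with an estimated correlation), with *secY* 6.57-fold, *tatC* 4.65-fold, cbdbA1693 3.86-fold and the insertase gene cbdbA1015 3.43-fold lower. The list also held the TatD family hydrolase gene cbdbA887 (2.12-fold lower) and the signal peptidase genes *lepB* (1.89-fold lower) and *lspA* (1.86-fold higher, with a log2 fold change of -1.21 on the scale of all counts). Complex I genes fell in 9 of 15 cases and rose in 2 (camera adjusted p = 0.027; adjusted p = 0.297 with an estimated correlation), with cbdbA842 8.96-fold, cbdbA846 7.49-fold and cbdbA684 4.44-fold lower. Of these, cbdbA842 and cbdbA846 lie in the stretch that also holds the nickel-dependent hydrogenase gene cbdbA850. The complex I cluster cbdbA874 to cbdbA885 (716512 to 726363), apart from that stretch, did not move one way, and the list's 9 lower genes include genes outside it. This cluster was chosen after its values were seen, and its genes cbdbA880 and cbdbA884 are outside the list. There cbdbA874 and cbdbA875, for subunits A and B, rose by log2 1.62 and 1.43, and turned to -0.48 and -0.67 on the scale of all counts. The genes cbdbA876, cbdbA877, *nuoH*, cbdbA880 and cbdbA881 did not pass (-0.11, 0.02, -0.50, -0.22 and -0.21; cbdbA877 -2.09 on the scale of all counts). At the far end *nuoK*, *nuoL*, cbdbA884 and cbdbA885 fell, with log2 fold changes of -1.28, -0.76, -1.18 and -2.16.

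Aminoacyl-tRNA synthetase genes fell in 13 of 19 cases and rose in 3 (camera adjusted p = 0.049; adjusted p = 0.417 with an estimated correlation). *tyrS* fell 3.45-fold, *thrS* 2.92-fold and the glycine enzyme gene cbdbA765 2.53-fold, whereas *cysS* rose 2.63-fold on the TMM scale and had a log2 fold change of -0.72 on the scale of all counts. The list of acetyl-CoA, pyruvate and citrate metabolism fell in 9 of 11 cases and rose in 2 (camera adjusted p = 0.049; adjusted p = 0.297 with an estimated correlation). Its members included the acetate--CoA ligase family gene cbdbA1077 (7.70-fold lower), the phenylacetate--CoA ligase family genes cbdbA894 and cbdbA988 (3.99-fold and 3.11-fold lower), which activate other acids, the indolepyruvate oxidoreductase genes cbdbA903 and *iorA* of aromatic amino acid breakdown (6.01-fold and 2.18-fold lower), and *panB* of pantothenate synthesis (5.10-fold higher). The call of *panB* was lost on the scale of all counts (log2 fold change 0.25, edgeR adjusted p = 0.36; 7.4e-20 to 0.36 over its alternatives). The synthetase call ended without 1,2,3-TCB replicate 1 (camera adjusted p = 0.060), 1,2,3-TCB replicate 2 (0.051) or 1,2,4-TCB replicate 2 (0.052), with a mean of at least 50 counts (0.084), with stable RNA left out (0.059) and with length classes centred (0.278; 0.011 to 0.417 over its alternatives). The acetyl-CoA call ended without 1,2,3-TCB replicate 2 (0.051), 1,2,4-TCB replicate 2 (0.059) or 1,2,4-TCB replicate 3 (0.057), with a mean of at least 50 counts (0.11), with stable RNA left out (0.059) and with length classes centred (0.148; 0.030 to 0.297 over its alternatives). The median coding length of the tested members was 1662 bp for the synthetases and 1290 bp for the acetyl-CoA list.

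The other 8 lists did not pass camera. On the scale of all counts MarR family regulators had 2 genes higher and 12 lower, and hydrogenase and maturation genes had 1 and 13. Two-component system genes had 0 higher and 36 lower of 43 tested there. MarR family regulators had 8 of 17 genes higher and 3 lower (camera adjusted p = 0.085; 0.013 to 0.55 over its alternatives), with cbdbA1622 31.2-fold and cbdbA1576 5.71-fold higher. The call of cbdbA1576 was lost on the scale of all counts (log2 fold change 0.41, edgeR adjusted p = 0.096; 6.0e-31 to 0.096 over its alternatives). Two-component system genes had 19 of 42 higher and 12 lower (camera adjusted p = 0.43); the histidine kinase gene cbdbA1608 fell 7.99-fold and cbdbA236 rose 4.00-fold, the latter with a log2 fold change of -0.11 on the scale of all counts. Hydrogenase and maturation genes had 7 of 15 higher and 2 lower (camera adjusted p = 0.33), with cbdbA850 in the complex I-like stretch 9.91-fold lower and *hypA* higher. Corrinoid salvage genes had 5 of 19 higher and 11 lower (camera adjusted p = 0.11), and the adenosylcobinamide amidohydrolase gene cbdbA81 was 7.83-fold lower. The level of cbdbA81 is uncertain, because its counts were not whole and it is 1 of 6 tested genes with the same product name. Among genes of that name, cbdbA1097 and cbdbA1499 had equal means of 2.50 CPM with 1,2,4-TCB, below the level of a count of 3. The 11 lower genes may therefore not be independent. Replication, cell division and RNA polymerase genes had 3 of 20 higher and 14 lower (camera adjusted p = 0.051; 0.023 to 0.42 over its alternatives, among them 0.047 without 1,2,3-TCB replicate 3 and 0.031 without 1,2,4-TCB replicate 1), with the sigma factor gene cbdbA1298 10.8-fold higher and the RNA polymerase alpha gene cbdbA466 4.54-fold lower. The mobile element and phage list had 7 of 9 lower and 1 higher (camera adjusted p = 0.090; 0.047 without 1,2,4-TCB replicate 1, and 0.047 to 0.55 over its alternatives). Its 7 lower genes are all CRISPR-associated, a defence against foreign DNA, with *casA* 4.32-fold lower, and its higher gene is the transposase gene cbdbA1487, at 3.23-fold, with a log2 fold change of -0.42 on the scale of all counts. One-carbon folate genes had 1 of 5 higher, cbdbA660 at 2.12-fold, and 1 lower, *glyA* at 3.63-fold (camera adjusted p = 0.84); cbdbA660 turned to -1.01 on the scale of all counts, and the list's median of 0.09 and mean of -0.14 differed in sign. The metal and oligopeptide transport list had 4 of 12 higher and 4 lower (camera adjusted p = 0.97), a median of -0.41 and a mean of 0.54, and 5 of its 8 called genes, cbdbA685, cbdbA846, cbdbA848, cbdbA1593 and cbdbA1720, encode iron-sulfur or cluster-binding proteins that are not transporters. No feature was annotated as a reductive dehalogenase membrane anchor, so that list was empty.

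**Figure D3:**
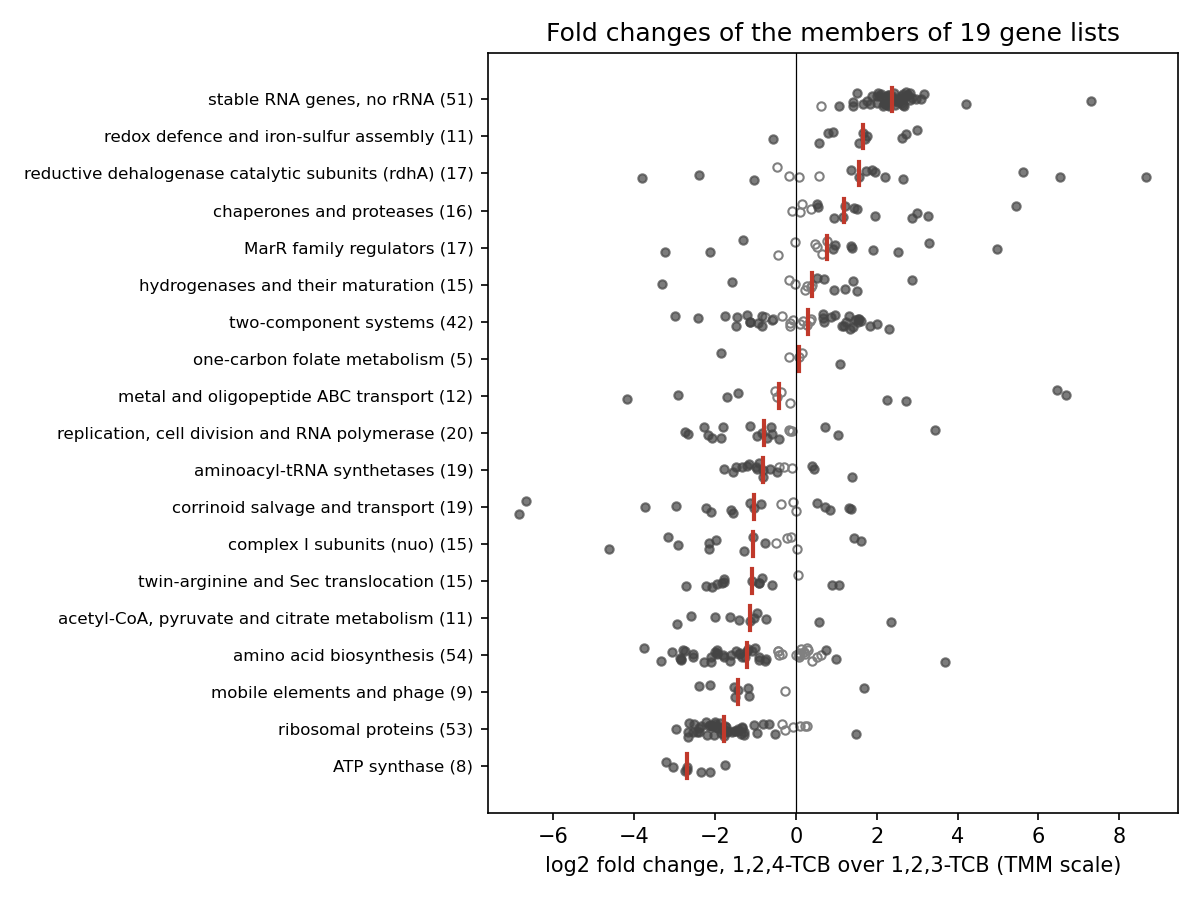
Log2 fold change, 1,2,4-TCB over 1,2,3-TCB, of every tested member of 19 gene lists on the TMM scale; filled points passed the edgeR test, open points did not, red bars are list medians and the number of tested members follows each name. All 8 ATP synthase genes lie below 0 and 50 of 51 stable RNA genes were called higher; the medians of the *rdhA*, chaperone and redox lists are above 0 here and lie at -0.55, -0.92 and -0.42 on the scale of all counts.

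Calls clustered along the chromosome (record NC_007356.1). Of 1011 called genes, 84.1% lay beside another tested gene called in the same direction, against a mean of 60.3% and a maximum of 68.2% in 100000 permutations of the calls (permutation p = 1e-05, the smallest they can give). Stretches of at least 4 neighbouring genes, each changed at least 4-fold in one direction, numbered 11, of which 5 were higher and 6 lower. They were found by scanning the table after the values were seen. Strand was not considered, so the genes of a stretch need not be transcribed together. The higher stretches included the 7 genes from cbdbA115 to cbdbA123 (108539 to 117692) around the molybdoenzyme anchor gene cbdbA120. They also included the 6 genes from cbdbA1034 to cbdbA1040 (835685 to 842891) around cbdbA1039. In these stretches cbdbA122 and cbdbA1040 lie on the opposite strand to the other genes. The lower ones included the 9 genes from cbdbA842 to cbdbA851 (687728 to 696816), the 5 aromatic pathway genes from *pheA* to cbdbA429 (354791 to 359568), the 6 ribosomal protein genes from *rpsS* to *rpsQ* (368695 to 371111) and the 4 ATP synthase genes from *atpA* to cbdbA539 (436835 to 441085).

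**Figure D4:**
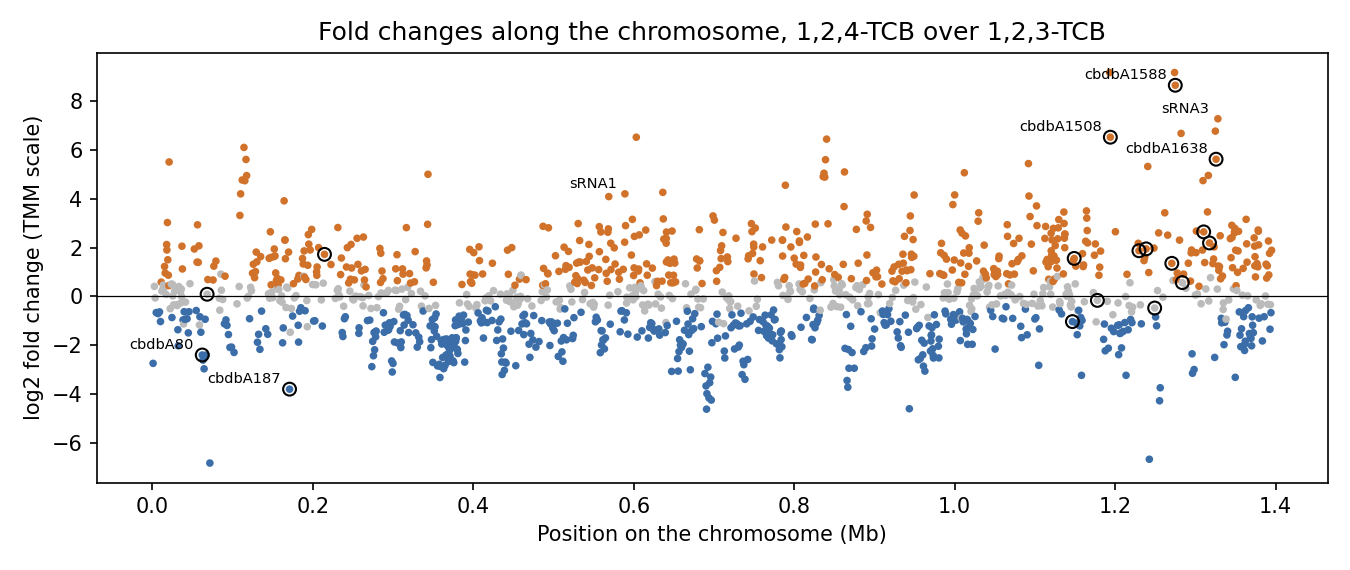
Log2 fold change on the TMM scale against chromosome position in megabases for the 1363 tested genes; orange points were called higher with 1,2,4-TCB, blue points lower, grey points did not pass, and black rings mark *rdhA* genes. The highest points are cbdbA1507 and cbdbA1587 at 9.19, beside the ringed cbdbA1508 and cbdbA1588, and on the scale of all counts the median of all genes shifts to -2.12.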

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

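The tests of the share of protein-coding counts and of shared reads were chosen after the results had been seen; those of other splits of the libraries were not. Signal was found in 5 of the 7 riboswitches, which name no gene and are part of no comparison above. Cobalamin riboswitches at positions 137269, 520808 and 527045 held 1267, 1118 and 1899.5 counts over the 6 libraries, a TPP riboswitch at 613091 held 778 and a cyclic di-GMP riboswitch at 1260708 held 485.5, all above the limit of 3 counts that a count of 0 allows. On the TMM scale the mean with 1,2,4-TCB was 9.71 times that with 1,2,3-TCB at 520808, 7.82 times at 527045, 4.67 times at 1260708, 3.42 times at 613091 and 1.44 times at 137269 (exact two-sided permutation p = 0.1 each, the smallest possible). On the scale of all counts these ratios were 2.28, 1.83, 1.07, 0.816 and 0.329 in the same order (exact permutation p = 0.1, 0.2, 0.9, 0.7 and 0.1), so that 613091 and 137269 turned. The genes that follow had log2 fold changes of 0.29 (cbdbA633, edgeR adjusted p = 0.22), 0.85 (*cobT*, 0.0067), 3.43 (cbdbA1572, 3.6e-06) and 0.24 (*thiC*, 0.35), at 520808, 527045, 1260708 and 613091 in turn; on the scale of all counts cbdbA633, *cobT* and *thiC* were at -1.84, -1.25 and -1.85.

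The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Each division other than the real one mixed the acceptors, so the acceptor difference widened the spread within its groups. Its counts are therefore not those of libraries without a difference. The real division gave 1011 called genes and the highest of the others gave 0, with 0 to 13 genes at an unadjusted p under 0.05 (edgeR); for *rdhA* genes the values were 13 and 0, and in each case 1 division reached the real value, the real one. For gene lists under camera's preset correlation the real division gave 11 and the highest of the others 13, so that 2 divisions gave as many; that other division, which put 1,2,4-TCB replicate 1 with 1,2,3-TCB replicates 1 and 2, called 0 genes.

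Protein-coding genes held 3.73 times less of all counts with 1,2,4-TCB. Depth was similar, since the smallest 1,2,4-TCB total was 0.966 times the largest 1,2,3-TCB total. Depth by itself does not lower a share of counts, so the totals do not bear on the cause. Counts taken by 6S and other small RNAs do not account for the lower coding share. The coding share of coding plus rRNA counts alone was 0.271 times as large. Nor was the loss limited to 1 length class. The class that kept most of its share, the 262 shortest coding genes of 69 to 423 bp, still had a median log2 ratio of -1.66. The medians went down with length to -2.58 in the longest class, so a loss graded by coding length is not excluded. A difference in mRNA content that came with the cultures or their harvest stays open, with a gap of 2.11 percentage points between the nearest libraries of the acceptors; growth state at harvest is not given per culture, so it and the acceptor cannot be told apart.

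The loci cbdbA1507 and cbdbA1587, both 270 bp long, had equal values in 6 of 6 libraries (tolerance 1e-06), consistent with reads shared between near-identical copies. For the adjacent *rdhA* genes, the ratio of cbdbA1508 to cbdbA1588 counts was 0.0756 to 0.102 with 1,2,4-TCB and 0.313 to 0.483 with 1,2,3-TCB. Among the 1,2,4-TCB libraries it varied only 1.35-fold, so that reads of cbdbA1588 placed at cbdbA1508 and a true rise of cbdbA1508 cannot be told apart without the gene sequences. No such explanation was tested for cbdbA1588 itself, whose counts were the larger.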

How the results depend on the processing

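Scaling to all counts with rRNA kept, unrounded counts, list terms matched without regard to case, the stable RNA list by its terms and centring of length classes were chosen after seeing the data. The scale decided the split of calls: 506 genes higher and 505 lower became 118 and 1018 with library size alone, and 87 and 1096 with all counts, because these scales keep the drop in coding counts that TMM removes. RLE, upper quartile, DESeq2, limma-voom, both filters, rRNA kept, stable RNA left out, a minimum change of 2-fold and unrounded counts each kept both counts within 1.5 times. Of the main calls 985 were shared with DESeq2 and 990 with limma-voom, all in the same direction. Leaving out a library gave 452 to 493 higher and 475 to 507 lower genes, 12 to 14 *rdhA* genes and 9 to 13 lists. Camera called 11 lists at the preset correlation and 0 with an estimated correlation (adjusted p 0.297 and above). The estimate lay below the preset 0.01 for the *rdhA* list (-0.015) and the acetyl-CoA list (0.005). Yet their unadjusted camera p rose from 0.023 to 0.070 and from 0.028 to 0.088. This argues against a higher correlation as the cause for these lists. In the other called lists the estimate lay above the preset value, and the cause was not tested further. In the other alternatives 8 to 13 lists were called, and 5 of the 19 lists, all without a call, kept their side of the threshold in each one run. Ignoring case in the list terms gave 12 lists: replication passed (camera adjusted p = 0.032; 0.023 to 0.42 over its alternatives) with 13 genes added to its 21, among them *thiL*, *guaA*, *carA* and *purD*, which serve other pathways. The stable RNA list by its terms left out sRNA1, sRNA2 and sRNA3 and gave 11 lists. Centring 5 classes of coding length in each library gave 9 lists. The synthetase list was lost (camera adjusted p = 0.278; 0.011 to 0.417 over its alternatives), as its median log2 fold change of -0.82 (quartiles -1.19 and -0.36) was -0.45 (-0.72 and 0.08) relative to genes of like length. The acetyl-CoA list was lost too (0.148; 0.030 to 0.297 over its alternatives), with a median of -1.12 (-1.82 and -0.85) that became -0.66 (-1.60 and -0.43).

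Of 83 named genes 65 kept direction and side in every alternative run. Upper quartile normalization moved the median log2 ratio of all tested genes to -0.23. Called values changed sign only with total-count scales, which keep the drop in coding counts that TMM removes. The uncalled cbdbA84 was also below 0 with upper quartile (-0.12) and without 1,2,4-TCB replicate 3 (-0.04). With library size alone log2 fold changes were -0.36 for *cysS*, -1.67 for cbdbA84, -0.016 for cbdbA243, -0.66 for cbdbA660, -0.19 for cbdbA1455, -0.058 for cbdbA1487, -0.39 for cbdbA1582 and -0.98 for cbdbA1625. With all counts they were -0.72 for *cysS*, -2.04 for cbdbA84, -0.11 for cbdbA236, -0.37 for cbdbA243, -1.01 for cbdbA660, -0.35 for cbdbA912, -0.55 for cbdbA1455, -0.42 for cbdbA1487, -0.14 for cbdbA1550, -0.75 for cbdbA1582 and -1.32 for cbdbA1625. Apart from these scales only cbdbA1582 and cbdbA1625 changed side: cbdbA1582 was lost with upper quartile (edgeR adjusted p = 0.065; 0.0022 to 0.45 over its alternatives) and without 1,2,3-TCB replicate 2, 1,2,4-TCB replicate 1 or 1,2,4-TCB replicate 3, and cbdbA1625 passed without 1,2,3-TCB replicate 3 or 1,2,4-TCB replicate 1.

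The *rdhA* share had a log2 ratio of -1.86, of -2.23 over all counts, of -0.30 over coding counts and of -1.999 to -1.73 when a library was left out. The share of called genes beside a like call was 75.9% on the same strand and 76.8% for 2-fold calls (permutation p = 1e-05 each). With the replicate number as a replicate block 474 genes were higher and 492 lower, 13 *rdhA* genes and 11 lists were called; the acetyl-CoA list was lost (camera adjusted p = 0.058) and replication passed (0.042). The numbers do not pair the libraries, since correlations of the deviations were -0.21, 0.01 and -0.17 for libraries with the same number, and no library correlated best with its own number. The median 95% interval reached 0.68 to either side on the log2 scale for the 341 genes with the lowest mean CPM and 0.45 to 0.49 for the 3 groups of more abundant genes.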

Other observations

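Apart from ssrA and *panB*, the genes in the first paragraph were named after their values were seen, and the tests of *rdhA* neighbours and regulators were chosen after the results had been seen; the test along the chromosome was not. Genes for ferrous iron uptake lay in a stretch that was higher with 1,2,4-TCB (1162443 to 1165839). There the Fur family regulator gene cbdbA1478, the FeoA gene cbdbA1477, the FeoB gene cbdbA1475, *smpB* and ssrA had log2 fold changes of 2.19 to 3.51. The first 3 of these genes lie on the minus strand, *smpB* and ssrA on the plus strand. Counts of cbdbA1478 with 1,2,4-TCB were 98, 395 and 113.5 in replicates 1, 2 and 3. Those of cbdbA1477 were 53.5, 164.5 and 54, and those of cbdbA1475 were 341.3, 1024.8 and 531.5. Replicate 2 thus held most of the counts of each of these genes. The pantothenate genes *panD*, *panB* and *panC* and their neighbour cbdbA779 (635796 to 638713) were also higher, by 2.34 to 4.27. A branched-chain amino acid transport stretch from cbdbA897 to cbdbA901 (734415 to 739591) was lower, by -3.40 to -2.66. All 3 stretches passed the edgeR test gene by gene (largest adjusted p 1.7e-04 in the first of them). On the scale of all counts the median of all genes shifts by -2.12, and there ssrA (0.09), cbdbA1475 (0.19), *panB* (0.25) and *panC* (0.25) no longer passed.

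A first hypothesis was that each *rdhA* gene is transcribed together with the small gene beside it on the same strand, as a gene for a membrane anchor would be. Across 12 such pairs the log2 fold changes of *rdhA* gene and neighbour had Spearman's rho of 0.90 (permutation p = 1.7e-04; adjusted p = 5.1e-04 over 3 hypotheses) and Pearson's r of 0.93, with the same sign in 10 of 12 pairs. Without the 2 pairs farthest from the median Pearson's r was 0.91, and without cbdbA1508, whose neighbour has the values of cbdbA1587, rho was 0.87. Pairs are genes, not independent replicates. Of all called genes, 84.1% lay beside a gene called in the same direction. The pairs were not compared with other neighbouring genes, so this permutation p does not set *rdhA* pairs apart from them. The exceptions were cbdbA1624, which rose by 2.19 beside cbdbA1623 at -0.19, and cbdbA1563 at -0.48 beside cbdbA1562 at 1.98. The small genes are annotated only as hypothetical proteins, so that their role is open; the values are consistent with co-transcription.

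A further hypothesis was that regulator genes change with the nearest *rdhA* gene. Across 17 pairs within 5000 bp rho was 0.38 (permutation p = 0.13; adjusted p = 0.19) and Pearson's r 0.21, which did not pass, with the same sign in 10 of 17 pairs. Without cbdbA1508, whose level is uncertain, rho was 0.56 over 16 pairs (permutation p = 0.027, not adjusted) and Pearson's r 0.39, so that the outcome rests on that pair and the hypothesis stays open. The MarR-type gene cbdbA1509 fell by 1.31 on the log2 scale beside cbdbA1508, and the response regulator gene cbdbA83 fell by 2.41 beside cbdbA84. A last hypothesis, lower gene dosage near the replication origin with 1,2,4-TCB, predicted fold changes that rise with distance from *dnaA*. Across 1309 protein-coding genes rho was -0.14 (circular-shift permutation p = 0.56), against the predicted direction.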
